A study of Mus musculus with 10 samples.

How the data were processed

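Whole lungs of mice were kept in RNAlater, total RNA was purified with Trizol and a column kit, mRNA was enriched and libraries were sequenced on an Illumina HiSeq instrument, per the labels. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and the GRCm38 genome were used. The counting tool and the annotation are not given in the sources used here, and neither is the strand of the libraries, so genes that overlap on opposite strands are uncertain. The deposited counts cover 53342 Ensembl genes for 10 libraries, of which 53237 identifiers are in GENCODE M21, used here for symbols, types and positions. Its first block of columns holds an expected count per gene and library, per the file headers: 86.9% to 90.6% of filled cells are not whole numbers at a tolerance of 0.001, and 34.4% of cells are blank and were read as 0. Genes without a read in any library number 7760. The second block holds log2 values that the authors normalised. Checked on 11649 genes with at least 200 reads, they equal the log2 count with 1 factor per library, less the median of the gene, to an SD of 6.8e-07. They repeat the counts and were not tested.

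Libraries were grouped by their labels into PBS (n = 4), HDM (n = 3) and SF-3-030+HDM (n = 3). The labels name DMSO for HDM and not for PBS, so HDM against PBS may also differ in solvent. With no group given the compound alone, SF-3-030 is seen on top of allergen in every library that had it. The labels do not say whether replicates are separate animals, so each p measures the spread between samples. Replicate numbers shared by the groups carried no pairing that could be seen: deviations of equally numbered libraries correlated at -0.63 to 0.19 across genes. Summed counts ran from 38667118 to 59083942 per library. Confidence intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

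Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. filterByExpr kept 26235 genes, libraries were scaled by TMM, and the 10 libraries were fitted in one quasi-likelihood model with a term per group. Each of the 3 comparisons was a contrast of that model, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. SE is the log2 fold change over the square root of the F statistic. CPM uses summed expected counts. For a gene without reads in a group, the fold is a bound at 3 counts over the group, and with 1 to 3 counts the ratio has an exact Poisson interval at 95%.

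The rule for named genes took the 8 largest rises and falls among called genes whose libraries do not overlap between groups and that average at least 1 CPM, without predicted genes and variable segments (4 each way in SF-3-030+HDM against PBS), a panel of 17 genes and up to 4 members with the smallest p in each of 32 gene lists. These lists cover type 2 cytokines and receptors, macrophage genes induced by IL-4 and IL-13, goblet, eosinophil, chemokine, neutrophil, NF-kB target, T cell, B cell, plasma cell, mast cell, monocyte and dendritic cell, interferon-stimulated, AP-1, ERK feedback, extracellular matrix, smooth muscle, alveolar type 1 and type 2, club, ciliated, endothelial, cell cycle, NRF2 target and clock genes, and markers of heart, adipose tissue, thymocytes, skeletal muscle, squamous epithelium and cartilage, erythroid cells and nerve. The groups, comparisons, lists, rule and first set of alternatives were set before the data were examined. A gene can be in more than 1 list. Single results of a few list genes are not reported here. Of the genes with libraries that do not overlap and 1 CPM, 452 were higher and 75 lower in HDM against PBS, 649 and 573 in SF-3-030+HDM against HDM, and 2203 and 1800 in SF-3-030+HDM against PBS.

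Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, with 64 tests adjusted together, and again with the correlation estimated for each list. fry tested whether the genes of a list move one way, and in its mixed form whether they change at all. List medians were also computed with genes of at most 3 counts in a group at their bound, which left each unchanged to 2 decimals.

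Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, fits of only the 2 groups compared, a block on the replicate number, a threshold of 0.01 and leaving out each library. Added after the data were seen were a covariate for Y-linked expression (Ddx3y above 10 CPM), a covariate for background (log2 of the summed olfactory and vomeronasal receptor CPM), and fits without the 3 libraries with Y-linked expression or the 3 with the most background. Median log2 fold changes over all tested genes were -0.0946, -0.0344 and -0.105 in the 3 comparisons with TMM, and -0.151, -0.186 and -0.307 with upper-quartile scaling, the only scaling that shifted any median by more than 0.1.

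In simulated data, 100 genes were changed at each of 2 log2 sizes. The test recovered 12%, 6% and 11% of size 1 in the 3 comparisons, and 53%, 52% and 56% of size 2. False calls were 2 of 67, 3 of 61 and 7 of 74. A moved list was called in both list comparisons (camera adjusted p = 6.41e-20 and 1.79e-15), and no unmoved list was. This does not cover lists of correlated genes. The strength of the shared control was judged from 20 simulated sets of unchanged groups. The data.table package had version 1.17.8. Lung function and histology named in the series text were not used.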

Results

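RNA was sequenced from whole mouse lung in 10 libraries of 3 groups. PBS, the control given saline, has 4 libraries. HDM, given house dust mite allergen into the nose on 5 days a week for 3 weeks, has 3 libraries, and its label also names the solvent DMSO. SF-3-030+HDM, given the compound SF-3-030 at 10 mg/kg into the nose 30 min before the allergen, has 3 libraries. The series title describes SF-3-030 as acting on selected functions of the kinases ERK1 and ERK2. All animals are labelled female BALB/c mice of 12 weeks. The labels name no group given the compound alone. Summed expected counts were 38667118, 56723177, 59083942 and 49928136 for PBS replicates 1 to 4, 51889105, 58424144 and 49531210 for HDM replicates 1 to 3, and 57277865, 55799329 and 59062738 for SF-3-030+HDM replicates 1 to 3. Levels are in CPM, counts scaled by the library total, and are given as mean ± SD with n = 4 for PBS and n = 3 for the other groups. Changes are log2 fold changes ± SE, and positions are on GRCm38.

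The 3 SF-3-030+HDM libraries lay together and apart from the other 7. Across genes, their log CPM correlated at 0.987 to 0.99 with one another and at 0.923 to 0.96 with the HDM libraries (genes are not independent replicates). PBS and HDM libraries correlated at 0.924 to 0.977, and the PBS libraries at 0.93 to 0.982 among themselves. The first principal component held 60% of the variance and the second 14.1%.

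**Figure D1:**
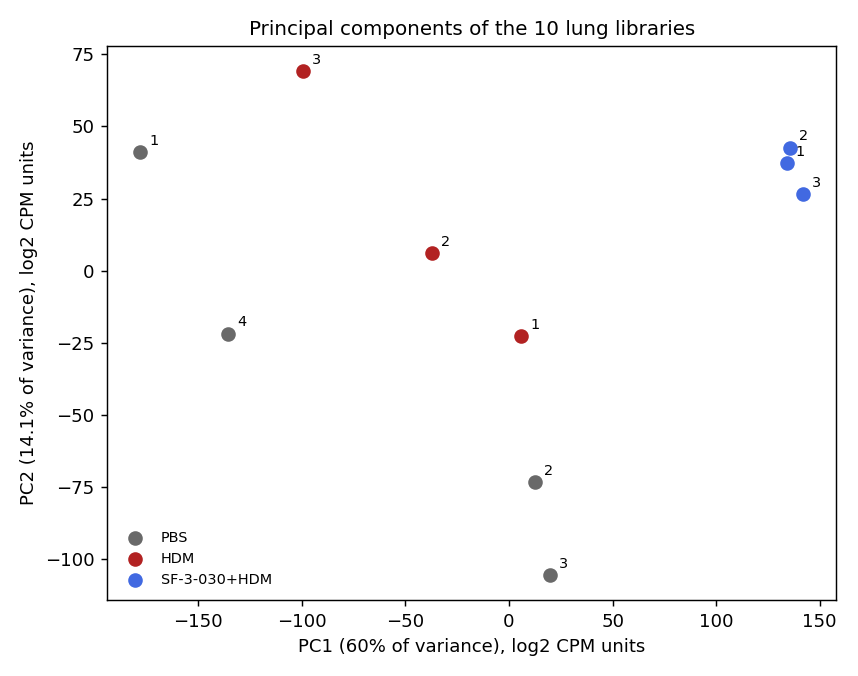
Principal components of the 10 libraries computed on log2 CPM of the tested genes, with the first component (60% of the variance) on the x axis and the second (14.1%) on the y axis; each point is a library, coloured by group. The 3 SF-3-030+HDM libraries lie at 134.1 to 142 on the first component, and the other 7 at -177.9 to 19.77.

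Genes that differ between inbred strains separated the libraries in the same way. H2-Ea-ps encodes a class II histocompatibility chain that C57BL/6 mice do not make. It stood at 331 to 432 CPM in the SF-3-030+HDM libraries and at 0.107 to 0.953 CPM in the other 7. Tpsab1, a mast cell tryptase missing in C57BL/6, stood at 11.9 to 15.4 against 0.000353 to 0.281 CPM. The guanylate-binding protein gene Gbp2b read 46.4 to 47.9 against 0.298 to 1.40 CPM. The opposite separation was seen for Trim12a, at 0.199 to 0.363 against 18.7 to 30.6 CPM. All of these genes were picked after their values were seen.

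Further label checks concerned sex and background. The Y-linked gene Ddx3y read 30.2 CPM in PBS replicate 2, 31.5 CPM in HDM replicate 2 and 20.4 CPM in HDM replicate 3, and at most 0.575 CPM in the other 7. Xist, transcribed from the inactive X chromosome, read 2.25, 0.835 and 2.71 CPM in those 3 libraries and at least 58.5 CPM in the others. Reads on olfactory and vomeronasal receptor genes, which lung does not use, summed to 469, 59.7, 49.2 and 308 CPM in PBS, to 90.4, 115 and 230 CPM in HDM and to 32.6, 31.1 and 16.0 CPM in SF-3-030+HDM. Genes with reads numbered 33371 to 39506 in PBS, 36334 to 39609 in HDM and 28929 to 30689 in SF-3-030+HDM libraries, and ribosomal RNA made up 0.859% to 2.56%, 1.81% to 2.33% and 0.379% to 1.59% of counts. Below, "without the Y-linked libraries" leaves out the 3 just named, and "without the high-background libraries" leaves out PBS replicates 1 and 4 and HDM replicate 3.

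**Figure D2:**
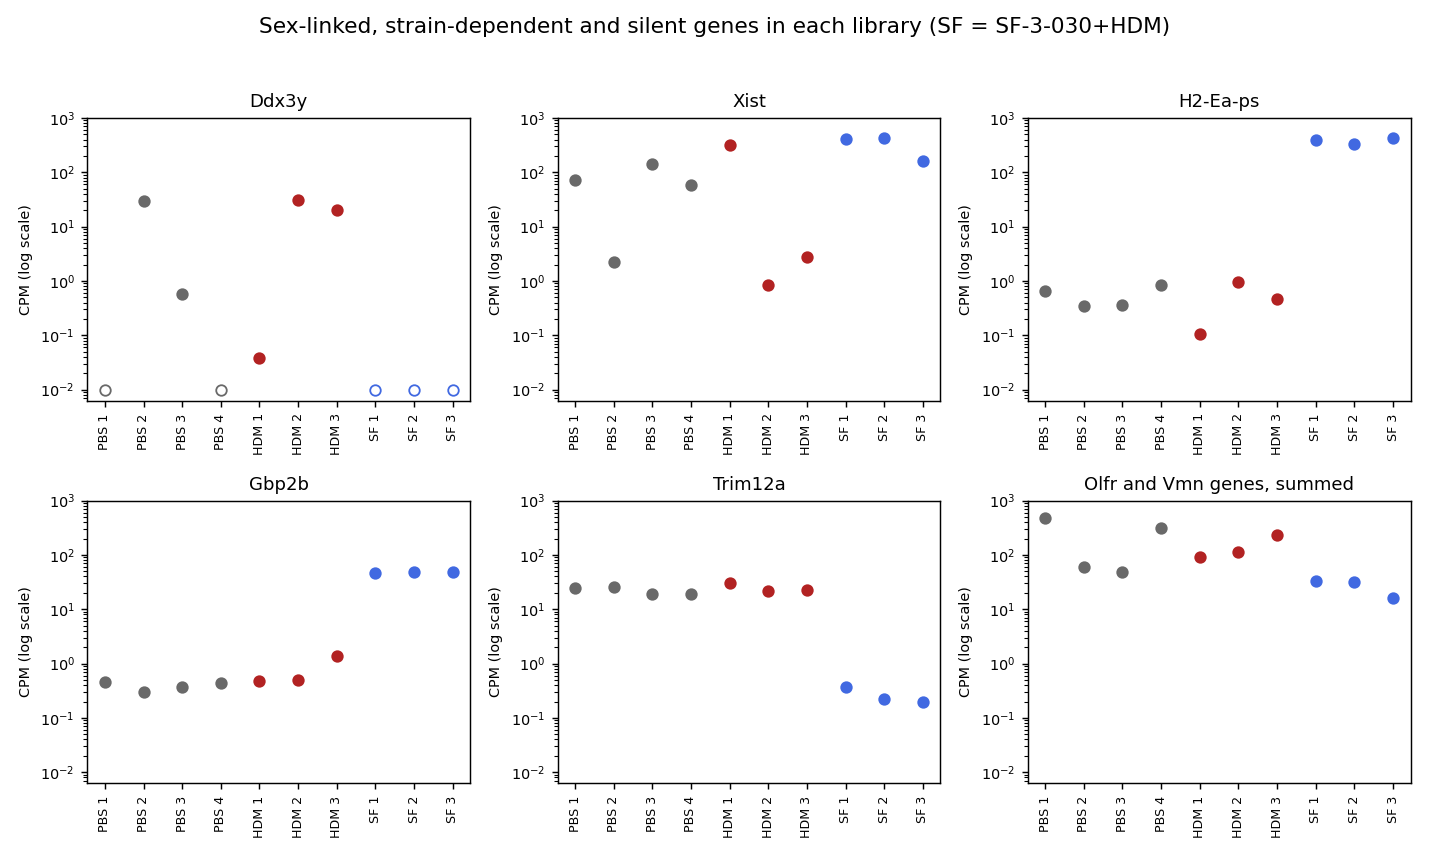
CPM on a log axis in each of the 10 libraries for Ddx3y, Xist, H2-Ea-ps, Gbp2b, Trim12a and the sum over olfactory and vomeronasal receptor genes; each point is a library, and open circles at 0.01 mark values below 0.01 CPM. Ddx3y is at 20.4 CPM or more in 3 libraries, and H2-Ea-ps is at 331 CPM or more in the SF-3-030+HDM libraries and below 1 CPM in the rest.

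HDM against PBS asks what repeated allergen does to the lung transcriptome. Plasma cell, macrophage, cell cycle and monocyte lists rose, and 608 of 26235 tested genes were higher with 77 lower. Ighg1, the constant region of the IgG1 heavy chain (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), rose 135-fold, from 108 ± 112 to 14200 ± 3200 CPM (log2 7.07 ± 0.73, edgeR adjusted p = 0.000684). Ighe, the IgE heavy chain, rose 68.5-fold from 0.67 ± 0.403 to 43.9 ± 28.2 CPM (adjusted p = 0.000566). Mmp12, the macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose 27-fold from 9.81 ± 5.55 to 265 ± 77.9 CPM (adjusted p = 0.000566). Scgb3a2, a secretoglobin of club cells (ENSMUSG00000038791, chromosome 18, 43764289 to 43767399), fell 2.85-fold from 1040 ± 307 to 349 ± 23.9 CPM (adjusted p = 0.00651).

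The largest changes named here and below are among genes that average 1 CPM or more in the higher group and whose libraries do not overlap between groups; variable immunoglobulin segments and predicted genes are left out, and some genes outside these limits changed more. The other genes with the largest rises were Npy, which encodes neuropeptide Y (log2 6.26 ± 0.48), the mast cell protease genes Mcpt1 (5.30 ± 0.71) and Mcpt2 (4.75 ± 0.59), Awat1, a wax ester synthase (4.72 ± 0.64), and the chemokine gene Ccl8 (4.60 ± 0.47). Their edgeR adjusted p values ran from 0.000214 for Npy to 0.00264 for Awat1. Immunoglobulin and mast cell protease genes have near-identical copies, so their assignment of reads is uncertain. The largest falls were in Cst8, a cystatin (-3.23 ± 0.35), Gal, which encodes the neuropeptide galanin (-3.07, adjusted p = 0.0266), Asgr1, a subunit of the asialoglycoprotein receptor (-2.92 ± 0.32), Gdpd2 (-2.59 ± 0.41), Pon1, a paraoxonase (-2.32 ± 0.33), Bex2 (-2.23 ± 0.29), Spon2 (-1.93 ± 0.25) and Upk1a, a uroplakin (-1.92 ± 0.33). Gal lost its call without PBS replicates 3 or 4 or HDM replicates 1, 2 or 3 (adjusted p 0.0614 to 0.134); the other 7 kept theirs without each single library.

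Genes that IL-4 and IL-13 induce in macrophages rose: 8 of 22 passed and 14 did not, with 16 higher when adjusted over the list alone (camera adjusted p = 2.18e-28; adjusted p = 0.0418 with an estimated correlation). Examples are Msr1, a scavenger receptor (2.48 ± 0.19, adjusted p = 0.000214), Clec7a, which encodes the beta-glucan receptor Dectin-1 (2.27 ± 0.22, adjusted p = 0.000566), Chil3, a chitinase-like protein (2.39 ± 0.40, adjusted p = 0.00867), and Arg1, arginase 1 (3.62 ± 0.62, adjusted p = 0.00912). Without single libraries, 7 of the 8 kept their calls, and Alox15, a lipoxygenase, did not (0.0512 to 0.112 without PBS replicates 2, 3 or 4, HDM replicates 1 or 3, or SF-3-030+HDM replicate 1). Monocyte and dendritic cell genes rose in 12 of 24, with 19 adjusted over the list alone (camera adjusted p = 2.76e-30; 0.0146 as an adjusted p with an estimated correlation). Among them were the complement genes C1qa (2.29 ± 0.34), C1qb (2.26 ± 0.33) and C1qc (2.42 ± 0.33), with edgeR adjusted p between 0.00312 and 0.00462.

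Plasma cell and immunoglobulin genes rose in 10 of 20, and in 13 adjusted over the list alone (camera adjusted p = 1.92e-40; adjusted p = 0.0435 with an estimated correlation). Besides Ighg1 and Ighe they included Iglc2, a light chain constant region (3.37 ± 0.45), and Pou2af1, a B cell coactivator (1.89 ± 0.25), both at an adjusted p of 0.00259. Immunoglobulin segments took 0.0816% to 1.17% of counts in PBS libraries and 3.97% to 8.12% in HDM libraries. B cell genes rose in 7 of 16, and in 14 adjusted over the list alone (camera adjusted p = 3.21e-27; adjusted p = 0.0867 with an estimated correlation). Cd72 (1.65 ± 0.17, adjusted p = 0.000684), Cd22 (1.48 ± 0.19, adjusted p = 0.00221), both inhibitory B cell receptors, and the transcription factor gene Spib (1.70 ± 0.23, adjusted p = 0.00262) kept their calls without each single library.

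T cell genes rose in 8 of 24, and in 18 adjusted over the list alone (camera adjusted p = 2.67e-23; adjusted p = 0.124 with an estimated correlation). The coreceptor gene Cd4 (1.91 ± 0.30, adjusted p = 0.00651) and the costimulator gene Icos (1.44 ± 0.24, adjusted p = 0.00891) kept their calls without each single library, and the other 6 did not. Type 2 cytokine and receptor genes were called higher as a list (camera adjusted p = 2.38e-05; adjusted p = 0.136 with an estimated correlation), with 5 of 21 higher adjusted over the list alone. Over all genes, Il21, a cytokine of follicular helper T cells, passed, and the other 20 did not. It rested on 2 counts in PBS and 96 in HDM, a ratio of 61.4 (counting interval 17 to 507; adjusted p = 0.00651). Of the allergic cytokines, Il4 stood at 0.16 ± 0.37 (adjusted p = 0.986), Il5 at 0.65 ± 0.67 (adjusted p = 0.958) and Il13 at 1.13 ± 0.73 (adjusted p = 0.752).

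Goblet cell and mucus genes were called higher as a list (camera adjusted p = 3.2e-08; adjusted p = 0.18 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone. Over all genes 5 of 26 rose. Itln1, the lectin intelectin 1 (3.18 ± 0.46, adjusted p = 0.00429), kept its call without each single library. Galnt6, which adds sugars to mucins (1.01, adjusted p = 0.0142), lost it without HDM replicate 2 (0.0909). The trefoil factor genes Tff2 (1.25, adjusted p = 0.0384) and Tff1 (3.47, adjusted p = 0.047) lost theirs without PBS replicates 1, 3 or 4, HDM replicate 3 or SF-3-030+HDM replicate 3 (0.0525 to 0.142 and 0.0523 to 0.237), Tff2 also without HDM replicate 1, and Tff1 also without PBS replicate 2, HDM replicate 2 or SF-3-030+HDM replicate 1. Slc26a4, an anion exchanger chosen after its value was seen (2.70 ± 0.64, adjusted p = 0.0478), lost it without PBS replicates 1, 3 or 4, HDM replicates 2 or 3, or any SF-3-030+HDM replicate (0.0624 to 0.287). The mucin gene Muc5ac stood at 2.05 ± 0.57 (adjusted p = 0.103; 0.0457 without PBS replicate 1 and 0.0417 without PBS replicate 2), and Clca1 at 1.48 ± 0.71 (adjusted p = 0.502).

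Chemokine genes rose in 8 of 32, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.06e-16; adjusted p = 0.152 with an estimated correlation). Ccl9 (2.59 ± 0.26, adjusted p = 0.000611), Ccl6 (2.29 ± 0.27, adjusted p = 0.00131) and Cxcl9, which draws T cells (3.15 ± 0.54, adjusted p = 0.00943), kept their calls without each single library. The eotaxin gene Ccl11 stood at 2.28 ± 0.56 (adjusted p = 0.0559; 0.0174 without PBS replicate 2 and 0.0212 without HDM replicate 1), and Ccl24 at 3.78 ± 1.03 (adjusted p = 0.0902; 0.0133 without HDM replicate 1). Eosinophil genes were called higher as a list (camera adjusted p = 0.000252; adjusted p = 0.214 with an estimated correlation). Of 14, Alox15 (2.92 ± 0.62, adjusted p = 0.0283), as above, and Cebpe, a myeloid transcription factor (2.71 ± 0.61, adjusted p = 0.0389), rose, and 5 did adjusted over the list alone. Cebpe lost its call without any PBS or SF-3-030+HDM replicate and without HDM replicates 1 or 3 (0.0584 to 0.18). Epx, eosinophil peroxidase, stood at 0.05 ± 0.53 (adjusted p = 0.997), and the receptor gene Siglecf at 0.61 ± 0.50 (adjusted p = 0.88).

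Cell cycle genes rose in 20 of 25, and in 23 adjusted over the list alone (camera adjusted p = 1.32e-45; adjusted p = 0.0146 with an estimated correlation). Top2a, topoisomerase 2 alpha, rose from 12.2 ± 3.57 to 36.5 ± 4.66 CPM (1.62 ± 0.23, adjusted p = 0.00383), with the mitotic kinase genes Aurkb (1.69 ± 0.24), Plk1 (1.41 ± 0.21) and Cdk1 (1.72 ± 0.27). Of the 20, 10 kept their calls without each single library, these 4 among them. Interferon-stimulated genes rose in 5 of 27, and in 15 adjusted over the list alone (camera adjusted p = 4.01e-14; adjusted p = 0.152 with an estimated correlation). Zbp1, a nucleic acid sensor (1.55 ± 0.25, adjusted p = 0.00693), kept its call without each single library. Oas1a (1.43, adjusted p = 0.0177), Oas2 (0.91, adjusted p = 0.0218) and Cxcl10 (2.27, adjusted p = 0.0273) lost theirs without PBS replicates 3 or 4 or HDM replicate 2 (0.0528 to 0.125), Oas2 also without HDM replicate 1 and the other pair also without HDM replicate 3. Irf7, chosen after its value was seen (1.42 ± 0.33, adjusted p = 0.0421), lost it without PBS replicates 2, 3 or 4, HDM replicates 2 or 3, or SF-3-030+HDM replicates 1 or 2 (0.054 to 0.174).

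Neutrophil genes were called lower as a list (camera adjusted p = 0.000375; adjusted p = 0.248 with an estimated correlation), and not without the Y-linked libraries (0.11). Of 19, S100a8, a calprotectin subunit, fell (-1.53 ± 0.32, adjusted p = 0.027; 0.0751 to 0.143 without HDM replicates 1, 2 or 3), and 2 fell adjusted over the list alone. Pro-inflammatory and NF-kB target genes were called higher as a list (camera adjusted p = 0.000375; adjusted p = 0.248 with an estimated correlation). The interleukin-1 antagonist gene Il1rn (1.49, adjusted p = 0.026) and the lipocalin gene Lcn2 (1.41, adjusted p = 0.0456) rose among 22, and 3 rose adjusted over the list alone. Il1rn lost its call without HDM replicates 1, 2 or 3 (0.0722 to 0.0856), and Lcn2 without these, PBS replicates 3 or 4, or any SF-3-030+HDM replicate (0.0593 to 0.212). Mast cell and basophil genes rose in 2 of 15, Mcpt1 and Mcpt2, with 3 higher and 1 lower adjusted over the list alone. The list was not called (camera adjusted p = 0.0689), but was without HDM replicate 1 (0.00104), 2 (0.0321) or 3 (0.0192), with the replicate block (0.0228) and in the mixed fry test (0.000712).

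ERK feedback and output genes were not called as a list (camera adjusted p = 0.227), except lower without PBS replicate 1 (0.0178) and with the Y-linked covariate (0.0309), and in the mixed fry test (0.00989). Dusp2, a phosphatase of ERK (1.07 ± 0.21, adjusted p = 0.0203), rose and Spry1, a Sprouty inhibitor (-0.67 ± 0.16, adjusted p = 0.0499), fell, both also adjusted over the list alone, and 20 of 22 did not pass. Dusp2 lost its call without PBS replicates 3 or 4 or HDM replicates 2 or 3 (0.0684 to 0.102), and Spry1 without every single library other than PBS replicate 1 (0.0963 to 0.227). Of 25 AP-1 and immediate early genes, edgeR called none over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called none. That list (camera adjusted p = 0.222) was called lower without PBS replicates 1 (0.00749) or 4 (0.0372), with the Y-linked covariate (4.12e-06) or the replicate block (0.0315), and higher without PBS replicate 2 (0.0288). Fos stood at -0.79 ± 0.72 (adjusted p = 0.921), Egr1 at -0.50 (adjusted p = 0.983), Fosl1 at -0.35 (adjusted p = 0.919), Myc at 0.47 (adjusted p = 0.461) and Dusp6 at -0.23 (adjusted p = 0.942).

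Extracellular matrix and remodelling genes rose in 6 and fell in 1 of 36, with 13 and 2 adjusted over the list alone (camera adjusted p = 4.83e-09; adjusted p = 0.248 with an estimated correlation). Mmp12 and the collagenase gene Mmp13 (3.46 ± 0.52, adjusted p = 0.00498) kept their calls without each single library. The collagen gene Col3a1 (1.32 ± 0.26, adjusted p = 0.0188) lost it without PBS replicates 3 or 4 or HDM replicates 2 or 3 (0.0573 to 0.0896), and Adam8 (1.22, adjusted p = 0.0128) without HDM replicate 3 (0.0633). The gene that fell, chosen after its value was seen, was the collagen gene Col12a1 (-1.07 ± 0.24, adjusted p = 0.0343), which lost its call without every single library other than PBS replicate 1 (0.0671 to 0.165).

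Club, alveolar type 1, ciliated and endothelial lists were called lower by camera with the preset correlation, and not with an estimated one. Directional fry also called the club (adjusted p = 0.045) and endothelial lists (0.0131), and not the alveolar type 1 (0.12) and ciliated lists (0.317). Club cell genes fell in 2 of 18, and in 7 adjusted over the list alone (camera adjusted p = 1.35e-09; adjusted p = 0.169 with an estimated correlation): Scgb3a2 and Cyp4b1, a cytochrome P450 (-1.08, adjusted p = 0.0194; 0.0541 to 0.0682 without PBS replicates 3 or 4 or HDM replicates 1 or 3). Endothelial genes were lower as a list (camera adjusted p = 3.4e-07; adjusted p = 0.0867 with an estimated correlation). Among 20, Eng, the TGF-beta coreceptor endoglin, fell (-0.76 ± 0.14, adjusted p = 0.0146; 0.0624 without HDM replicate 2 and 0.0628 without HDM replicate 3), and 3 fell adjusted over the list alone. The alveolar type 1 list was lower (camera adjusted p = 0.000252; adjusted p = 0.343 with an estimated correlation), with no member of 14 passing in edgeR, 1 lower adjusted over the list alone, 4 lower at an unadjusted p under 0.05, 1 lower in DESeq2 and none in limma-voom. The ciliated list was lower too (camera adjusted p = 0.00199; adjusted p = 0.576 with an estimated correlation), but not without HDM replicate 3 (0.321) or without the Y-linked libraries (0.535). None of its 22 genes passed in edgeR, DESeq2 or limma-voom, nor adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05.

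Markers of heart muscle moved with the groups too, and their source within the samples was not tested. Heart muscle genes were lower as a list (camera adjusted p = 8.97e-09; adjusted p = 0.248 with an estimated correlation). Of 17, Tnni3, cardiac troponin I, fell (-1.15 ± 0.23, adjusted p = 0.0201; 0.0592 to 0.143 without PBS replicate 3 or HDM replicates 1 or 2), and 9 fell adjusted over the list alone.

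Across the 32 lists, 14 were called higher and 9 lower in this comparison, and 4 of these 23 calls held with an estimated correlation: the macrophage, plasma cell, monocyte and cell cycle lists. Of the genes called higher, 458 were protein-coding and 130 were immunoglobulin segments. Without the Y-linked libraries 241 genes were higher and 9 lower, and without the high-background libraries 208 and 35. The count of 608 became 393 without PBS replicate 3, 359 without PBS replicate 4 and 276 without HDM replicate 2. The count of 77 became 190, 33 and 34 without PBS replicates 1, 3 and 4, 45, 27 and 36 without HDM replicates 1 to 3, and 42, 48 and 49 without SF-3-030+HDM replicates 1 to 3.

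SF-3-030+HDM against HDM asks how the allergen-exposed lung differs when SF-3-030 is given before the allergen. Mast cell, B cell and type 2 genes were higher and club cell, alveolar type 2 and heart muscle genes were lower, within 901 higher and 1590 lower genes of 26235; of these lists the mast cell list alone held its call with an estimated correlation. Cpa3, the mast cell carboxypeptidase (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181), rose 7.02-fold from 0.653 ± 0.0497 to 4.69 ± 0.77 CPM (log2 2.81 ± 0.25, edgeR adjusted p = 6e-05). Epx, eosinophil peroxidase (ENSMUSG00000052234, chromosome 11, 87864000 to 87875536), rose 21.7-fold from 0.105 ± 0.0485 to 2.24 ± 0.514 CPM (adjusted p = 0.000721). Scgb3a2 of club cells fell 6.95-fold from 349 ± 23.9 to 51.4 ± 13.6 CPM (adjusted p = 7.99e-05). Sftpb, which encodes surfactant protein B (ENSMUSG00000056370, chromosome 6, 72304610 to 72314371), fell 2.08-fold from 4500 ± 322 to 2190 ± 169 CPM (adjusted p = 0.00464).

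The largest changes included strain-dependent genes. The 3 SF-3-030+HDM libraries are the ones that stood apart in strain-type genes above, and this holds beside every gene group of this comparison and the next. H2-Ea-ps (ENSMUSG00000036322, chromosome 17, 34341959 to 34344645) was 713-fold higher (9.48 ± 0.67, adjusted p = 1.01e-05), and AY761185, with no count in HDM, at least 54.2-fold higher. Also higher were the interferon-inducible genes Ifi202b (7.84 ± 0.74) and Ifi44l (6.75 ± 0.85), the protease inhibitor gene Serpina3h (6.94 ± 0.44), Tpsab1 (6.40 ± 0.65), Hal, which encodes histidine ammonia-lyase (6.30 ± 0.37), and the potassium channel gene Kcnj14 (6.25 ± 0.80). Ifi202b and Serpina3h may share reads with near-identical copies and are uncertain. Whether H2-Ea-ps shares reads with other genes was not tested. Within the limits above, the largest falls were in Spink5, a protease inhibitor (-7.47 ± 0.58, from 6.41 ± 1.29 CPM), Ankrd63 (-6.83 ± 0.48) and 6 genes with at most 3 counts in SF-3-030+HDM. Of the latter, Cldn34c1 was at least 105-fold lower, Sall4 at least 82.2-fold and Vmn1r173 at least 63.9-fold. The HDM to SF-3-030+HDM ratio was 275 for Duxf3 (counting interval 94 to 1330), 204 for AW822073 (36.5 to 8040) and 130 for Trim71 (44.5 to 630). Vmn1r173, AW822073 and Trim71 lost their calls without SF-3-030+HDM replicates 1, 2 or 3 (edgeR adjusted p 0.0552 to 0.0916), and Sall4 without these or HDM replicates 2 or 3 (0.063 to 0.0947).

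Mast cell and basophil genes rose in 10 of 15, and in 12 adjusted over the list alone (camera adjusted p = 3.18e-17; adjusted p = 0.0146 with an estimated correlation). Beside Cpa3 and Tpsab1 were the protease genes Mcpt4 (3.16 ± 0.42, adjusted p = 0.000974) and Mcpt2 (3.28 ± 0.51, adjusted p = 0.00296). Without single libraries 8 of the 10 kept their calls. Type 2 cytokine and receptor genes rose in 7 of 21, also 7 adjusted over the list alone (camera adjusted p = 0.000163; adjusted p = 0.152 with an estimated correlation). Il1rl1, the receptor of IL-33 (1.99 ± 0.25, adjusted p = 0.000657), and Cish, an inhibitor of cytokine signalling (1.29 ± 0.20, adjusted p = 0.00299), kept their calls without each single library. Il13 rose from 0.858 ± 0.979 to 5.97 ± 1.52 CPM (2.79 ± 0.78, adjusted p = 0.0461) and Il4 from 0.653 ± 0.177 to 1.73 ± 0.194 CPM (1.38 ± 0.39, adjusted p = 0.0476). Both lost their calls without PBS replicate 4, HDM replicates 1 or 2 or any SF-3-030+HDM replicate (Il13 0.0506 to 0.134, Il4 0.0648 to 0.149), Il4 also without HDM replicate 3. Il13ra2, the IL-13 decoy receptor (3.88 ± 0.86, adjusted p = 0.021), and Il5ra (1.64 ± 0.36, adjusted p = 0.0212) lost theirs without HDM replicate 2 or SF-3-030+HDM replicates 1 or 2 (0.0751 to 0.101), and Il5ra also without HDM replicate 3 (0.0636). Il5 stood at 1.91 ± 0.72 (adjusted p = 0.103; 0.0395 without HDM replicate 3).

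Goblet cell and mucus genes rose in 6 of 26, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000352; adjusted p = 0.343 with an estimated correlation). Itln1 rose from 6.43 ± 2.93 to 147 ± 37.6 CPM (4.53 ± 0.51, adjusted p = 0.000319), with Pigr, which carries IgA across epithelium (2.16 ± 0.40, adjusted p = 0.00829), and Tff1 (3.57 ± 0.74, adjusted p = 0.0154). Tff1 lost its call without HDM replicate 2 or SF-3-030+HDM replicates 1 or 3 (0.0613 to 0.0677). Muc5ac stood at 0.31 ± 0.61 (adjusted p = 0.778) and Clca1 at 1.05 ± 0.77 (adjusted p = 0.399). Macrophage genes induced by IL-4 and IL-13 rose in 3 of 22, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00217; adjusted p = 0.499 with an estimated correlation). The list was not called with background as a covariate (0.23). The 3 were the C-type lectin genes Cd209d (1.89 ± 0.39, adjusted p = 0.015) and Cd209e (2.68 ± 0.77, adjusted p = 0.0498) and Mmp12 (1.70 ± 0.46, adjusted p = 0.0427). Cd209d lost its call without HDM replicate 2 or SF-3-030+HDM replicate 3 (0.052 to 0.0634), and the other pair without any HDM or SF-3-030+HDM replicate (0.0623 to 0.143), Cd209e also without PBS replicate 4. Arg1 stood at 2.21 ± 0.64 (adjusted p = 0.0524), with 0.0453 without PBS replicate 1 and 0.000363 without HDM replicate 3. Chil3 stood at 0.17 ± 0.42 (adjusted p = 0.827) and Retnla, which encodes the resistin-like protein RELM-alpha, at 1.99 ± 0.83 (adjusted p = 0.137; 0.0475 without HDM replicate 3).

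Eosinophil genes were not called as a list (camera adjusted p = 0.126), except higher without HDM replicate 1 (0.0452) or SF-3-030+HDM replicate 2 (0.0244), and in the mixed fry test (1.84e-05). Epx and Il5ra rose, the ribonuclease gene Ear1 fell (-3.35 ± 0.59, adjusted p = 0.00605; near-identical copies make it uncertain), and 11 of 14 did not pass, the same counts as adjusted over the list alone. Siglecf stood at -0.11 ± 0.54 (adjusted p = 0.918). Chemokine genes rose in 6 and fell in 4 of 32, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.618 with an estimated correlation). The list was not called without PBS replicate 1 (0.0566), HDM replicate 1 (0.194) or SF-3-030+HDM replicate 3 (0.077), at a filter of 1 CPM in 3 libraries (0.235) or with background as a covariate (0.187). Cxcl5, a neutrophil attractant, rose from 0.725 ± 0.853 to 32.6 ± 13 CPM (5.53 ± 0.86, adjusted p = 0.00287), and Cxcl13, which draws B cells, rose by 2.46 ± 0.41 (adjusted p = 0.00469). Ccl11 rose from 24.5 ± 16.6 to 180 ± 23.8 CPM (2.85 ± 0.62, adjusted p = 0.0193), a call lost without HDM replicate 2 or any SF-3-030+HDM replicate (0.0505 to 0.0708). The 4 that fell were Ccl19 (-2.03, adjusted p = 0.0109) and, chosen after their values were seen, Cxcl14 (-1.17), Ccl21a (-0.75) and Cx3cl1 (-0.65). Each of the 4 lost its call without HDM replicate 2 or SF-3-030+HDM replicates 1 or 2, Cxcl14 and Cx3cl1 also without SF-3-030+HDM replicate 3, Cx3cl1 and Ccl21a without HDM replicate 3, and Ccl21a without HDM replicate 1 or PBS replicate 4 (0.0501 to 0.172 over these). Ccl24 stood at 1.45 ± 1.01 (adjusted p = 0.375; 0.00496 without HDM replicate 3).

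Neutrophil genes rose in 3 of 19, also 3 adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.278 with an estimated correlation). They were the chemokine receptor gene Cxcr2 (1.67 ± 0.29, adjusted p = 0.00537), Retnlg (1.71 ± 0.41, adjusted p = 0.0302) and Csf3r, the G-CSF receptor (1.42 ± 0.37, adjusted p = 0.0367). Without HDM replicate 2 or any SF-3-030+HDM replicate Retnlg (0.0514 to 0.0954) and Csf3r (0.0886 to 0.121) lost their calls, Csf3r also without HDM replicate 3. Pro-inflammatory and NF-kB target genes rose in 2 of 22, also 2 adjusted over the list alone (camera adjusted p = 0.00487; adjusted p = 0.369 with an estimated correlation; 0.238 with background as a covariate). These were Il1a, interleukin-1 alpha (1.73 ± 0.28, adjusted p = 0.00324), and Il1rn (1.34, adjusted p = 0.0331), which lost its call without any HDM or SF-3-030+HDM replicate (0.0631 to 0.107).

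B cell genes rose in 9 of 16, and in 12 adjusted over the list alone (camera adjusted p = 4.83e-10; adjusted p = 0.248 with an estimated correlation). Pax5, the B cell lineage factor, rose from 23.8 ± 3.21 to 72.7 ± 16.9 CPM (1.57 ± 0.25, adjusted p = 0.00308) and Cr2, a complement receptor, by 1.74 ± 0.29 (adjusted p = 0.00465); the other 7 lost their calls without at least 1 library, as Ms4a1 did without SF-3-030+HDM replicate 1 (0.0534). Plasma cell and immunoglobulin genes were not called as a list (camera adjusted p = 0.937), except higher with the Y-linked covariate (0.00899), and in the mixed fry test (0.0209). Ighe (2.39 ± 0.55, adjusted p = 0.0246) and Pou2af1 (2.14-fold, adjusted p = 0.0322) rose, and Ighg2c (-5.70 ± 1.57, adjusted p = 0.0438) and Ighg3 (-2.54 ± 0.72, adjusted p = 0.0475), constant regions of other IgG classes, fell, with 2 higher and 3 lower adjusted over the list alone. Ighg2c is the C57BL/6-type form of its gene, a strain-type difference that stands beside its fall. All 4 lost their calls without SF-3-030+HDM replicates 1 or 2 (0.065 to 0.159), and without HDM replicate 2 (Ighe 0.0717, Ighg2c 0.114, Ighg3 0.11), HDM replicate 1 (Pou2af1 0.0715, Ighg2c 0.053, Ighg3 0.0982), HDM replicate 3 (Pou2af1 0.0925, Ighg2c 0.0661) or SF-3-030+HDM replicate 3 (Pou2af1 0.0858, Ighg2c 0.125, Ighg3 0.103).

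Alveolar type 2 genes fell in 6 of 19, with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.499 with an estimated correlation). Acoxl (-2.71 ± 0.26, adjusted p = 0.000114), the fatty acid elongase gene Elovl1 (-1.25 ± 0.16, adjusted p = 0.00092) and Sftpb kept their calls without each single library. Napsa, an aspartic protease that processes surfactant protein (from 516 ± 51 to 259 ± 31.3 CPM, adjusted p = 0.0129), lost its call without SF-3-030+HDM replicates 1 (0.0751) or 2 (0.0725). Club cell genes fell in 3 of 18, and in 4 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.532 with an estimated correlation). The list lost its call without HDM replicate 2 (0.0844) or SF-3-030+HDM replicate 2 (0.118). Among them were Scgb3a2 and Cyp2f2 (-1.15 ± 0.28, adjusted p = 0.032), the latter of which lost its call without HDM replicate 2 or any SF-3-030+HDM replicate (0.0912 to 0.13). Alveolar type 1 genes were not called as a list (camera adjusted p = 0.146), but were lower with background as a covariate (0.00319) and at 1 CPM in 3 libraries (0.0219), and called in the mixed fry test (0.0147). Of 14, the water channel gene Aqp5 fell (-1.15 ± 0.20, adjusted p = 0.00545), and 2 fell adjusted over the list alone.

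Heart muscle genes fell in 10 of 17, and in 16 adjusted over the list alone (camera adjusted p = 1.45e-10; adjusted p = 0.214 with an estimated correlation). The atrial light chain genes Myl7, from 34.3 ± 6.62 to 9.73 ± 3.62 CPM (-1.83 ± 0.31, adjusted p = 0.00448), and Myl4 (-1.48 ± 0.25, adjusted p = 0.00533) kept their calls without each single library, and the other 8 did not. Adipose genes fell in 7 and rose in 1 of 13, with 10 and 1 adjusted over the list alone (camera adjusted p = 6.43e-05; adjusted p = 0.343 with an estimated correlation). Among these were the lipid droplet genes Cidec (-3.36 ± 0.52, adjusted p = 0.00271) and Plin1 (-2.02 ± 0.38, adjusted p = 0.00874) and Cfd, the adipokine adipsin (-2.54 ± 0.48, adjusted p = 0.00901). The gene that rose, chosen after its value was seen, was Cidea (1.64 ± 0.42, adjusted p = 0.0348), a call lost without PBS replicate 4, HDM replicates 1 or 3 or SF-3-030+HDM replicates 1 or 3 (0.0503 to 0.139).

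ERK feedback and output genes were not called as a list (camera adjusted p = 0.41), except in the mixed fry test (0.0297). Of 22, Spry4, a Sprouty inhibitor, rose (1.19 ± 0.25, adjusted p = 0.0174), also adjusted over the list alone, a call lost without HDM replicate 2 or SF-3-030+HDM replicates 1 or 2 (0.0572 to 0.0797). AP-1 and immediate early genes were not called either (camera adjusted p = 0.937; median -0.03 and mean -0.16, while the test pointed up), except higher with the Y-linked covariate (0.00452) and lower with the background covariate (0.018). Of 25, Myc rose (0.80 ± 0.23, adjusted p = 0.0498), but not adjusted over the list alone. It lost its call without every single library other than PBS replicate 1 and HDM replicate 3 (0.0514 to 0.137). Fos stood at -0.52 ± 0.76 (adjusted p = 0.695), Egr1 at -1.50 ± 0.92 (adjusted p = 0.31), Fosl1 at 0.20 ± 0.34 (adjusted p = 0.741) and Dusp6 at 0.39 ± 0.24 (adjusted p = 0.313). Cell cycle genes were called higher as a list (camera adjusted p = 1.76e-05; adjusted p = 0.287 with an estimated correlation). Pcna (0.55 ± 0.15, adjusted p = 0.0453) and Rrm2 (0.94 ± 0.27, adjusted p = 0.0482), both needed for DNA synthesis, rose among 25, none rose adjusted over the list alone, and 11 were higher at an unadjusted p under 0.05. Both lost their calls without PBS replicate 4 or any HDM or SF-3-030+HDM replicate (0.0532 to 0.142), Pcna also without PBS replicate 2.

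In this comparison 9 lists were called higher and 5 lower, and of these 14 the mast cell list held with an estimated correlation. Olfactory and vomeronasal receptor genes gave 109 of the lower calls, and 884 of the 1590 lower genes averaged under 1 CPM, 706 averaged 1 CPM or more and 337 averaged 10 CPM or more. Without the Y-linked libraries 265 genes were higher and 278 lower, and without the high-background libraries 1244 and 1864. The 901 higher calls became 1458 without PBS replicate 1, 354 and 514 without HDM replicates 2 and 3, and 323, 328 and 482 without SF-3-030+HDM replicates 1 to 3. The 1590 lower calls became 992 without PBS replicate 4, 464 and 671 without HDM replicates 2 and 3, and 349, 301 and 476 without SF-3-030+HDM replicates 1 to 3. Of all calls 36.2% were higher, with 60.3% in limma-voom, 50.1% at a threshold of 0.01, 50% with the Y-linked covariate, and 48.1%, 52.1% and 50.3% without SF-3-030+HDM replicates 1 to 3.

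**Figure D3:**
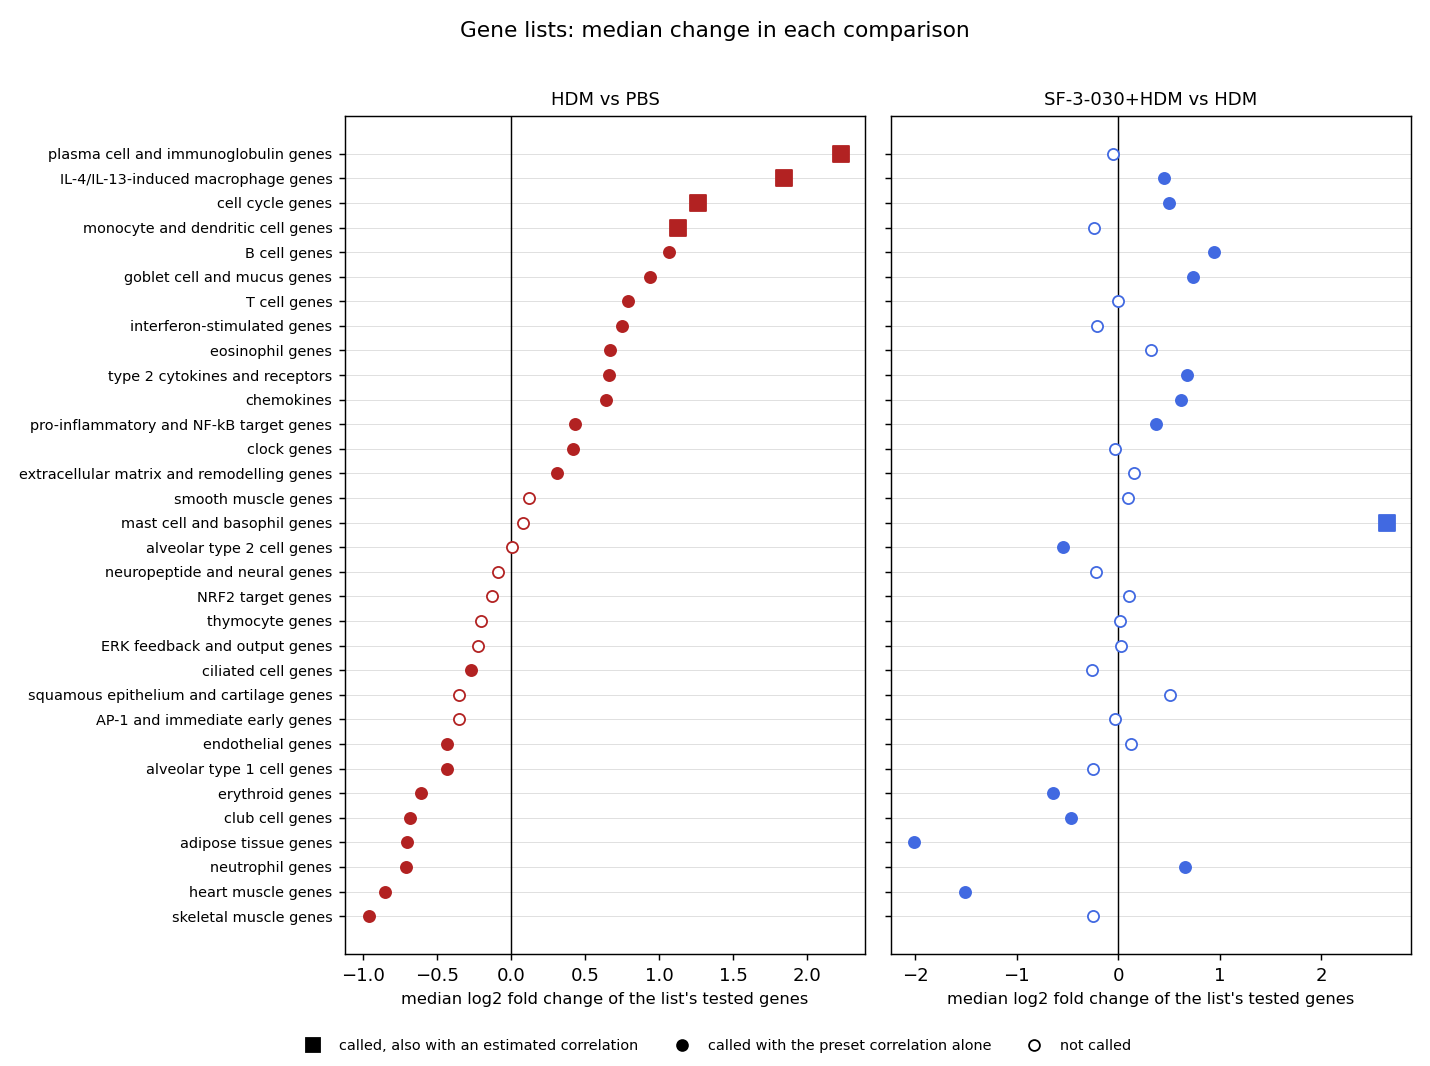
Median log2 fold change of the tested members of each of the 32 fixed gene lists on the x axis, in HDM against PBS and in SF-3-030+HDM against HDM; squares are lists called also with an estimated correlation, filled circles lists called with the preset correlation alone and open circles lists not called. The plasma cell list has the largest median in HDM against PBS (2.23), and the mast cell list in SF-3-030+HDM against HDM (2.65).

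SF-3-030+HDM against PBS gives the distance of the treated, allergen-exposed lung from the unexposed one. Of 26235 genes, 3101 were higher and 4741 lower, and gene lists were not tested in this comparison. Il13 rose by 3.92 ± 0.74 (edgeR adjusted p = 0.00343), Il5 by 2.56 ± 0.67 (adjusted p = 0.016) and Il4 by 1.54 ± 0.36 (adjusted p = 0.00988). Epx rose 22.5-fold (adjusted p = 0.000118), the eotaxin genes Ccl11 by 5.13 ± 0.61 (adjusted p = 0.000178) and Ccl24 by 5.23 ± 1.07 (adjusted p = 0.0054), and Retnla 22.5-fold from 543 ± 444 to 12300 ± 1730 CPM (adjusted p = 0.0028). Arg1 (5.83 ± 0.67, adjusted p = 0.000142), Chil3 (2.56 ± 0.41, adjusted p = 0.00113), Muc5ac (2.36 ± 0.58, adjusted p = 0.0125), Clca1 (2.53 ± 0.72, adjusted p = 0.0235) and Myc (1.27 ± 0.21, adjusted p = 0.00166) rose too. Without SF-3-030+HDM replicate 2 Il5 lost its call (0.0616), and without replicates 1 (0.0856) or 3 (0.0644) Clca1 lost its own.

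The largest rises in that comparison were in H2-Ea-ps (9.50 ± 0.58), Sprr2a3, a cornified envelope gene with near-identical copies (9.08 ± 0.90), Mcpt1 (8.69 ± 0.74) and Ighe, from 0.67 ± 0.403 to 238 ± 79.5 CPM (8.49 ± 0.65). With no count in SF-3-030+HDM, the largest falls were at least 145-fold for Cldn34c1, 131-fold for Sall4, 122-fold for Skint3 and 94.6-fold for Vmn1r173. Background was again not tested. Siglecf stood at 0.50 (adjusted p = 0.475), Fos at -1.31 (adjusted p = 0.194), Fosl1 at -0.15 (adjusted p = 0.741), Egr1 at -2.00 (adjusted p = 0.112; 0.0321 without PBS replicate 1) and Dusp6 at 0.16 (adjusted p = 0.626). Of the lower genes, 237 were olfactory or vomeronasal receptor genes and 2781 averaged under 1 CPM. Without the Y-linked libraries 3044 genes were higher and 4677 lower, and without the high-background libraries 2711 and 2636. The higher count became 1894 and 1880 without SF-3-030+HDM replicates 1 and 2. The lower count became 2857 without PBS replicate 4, and 2124, 2013 and 2513 without SF-3-030+HDM replicates 1 to 3.

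**Figure D4:**
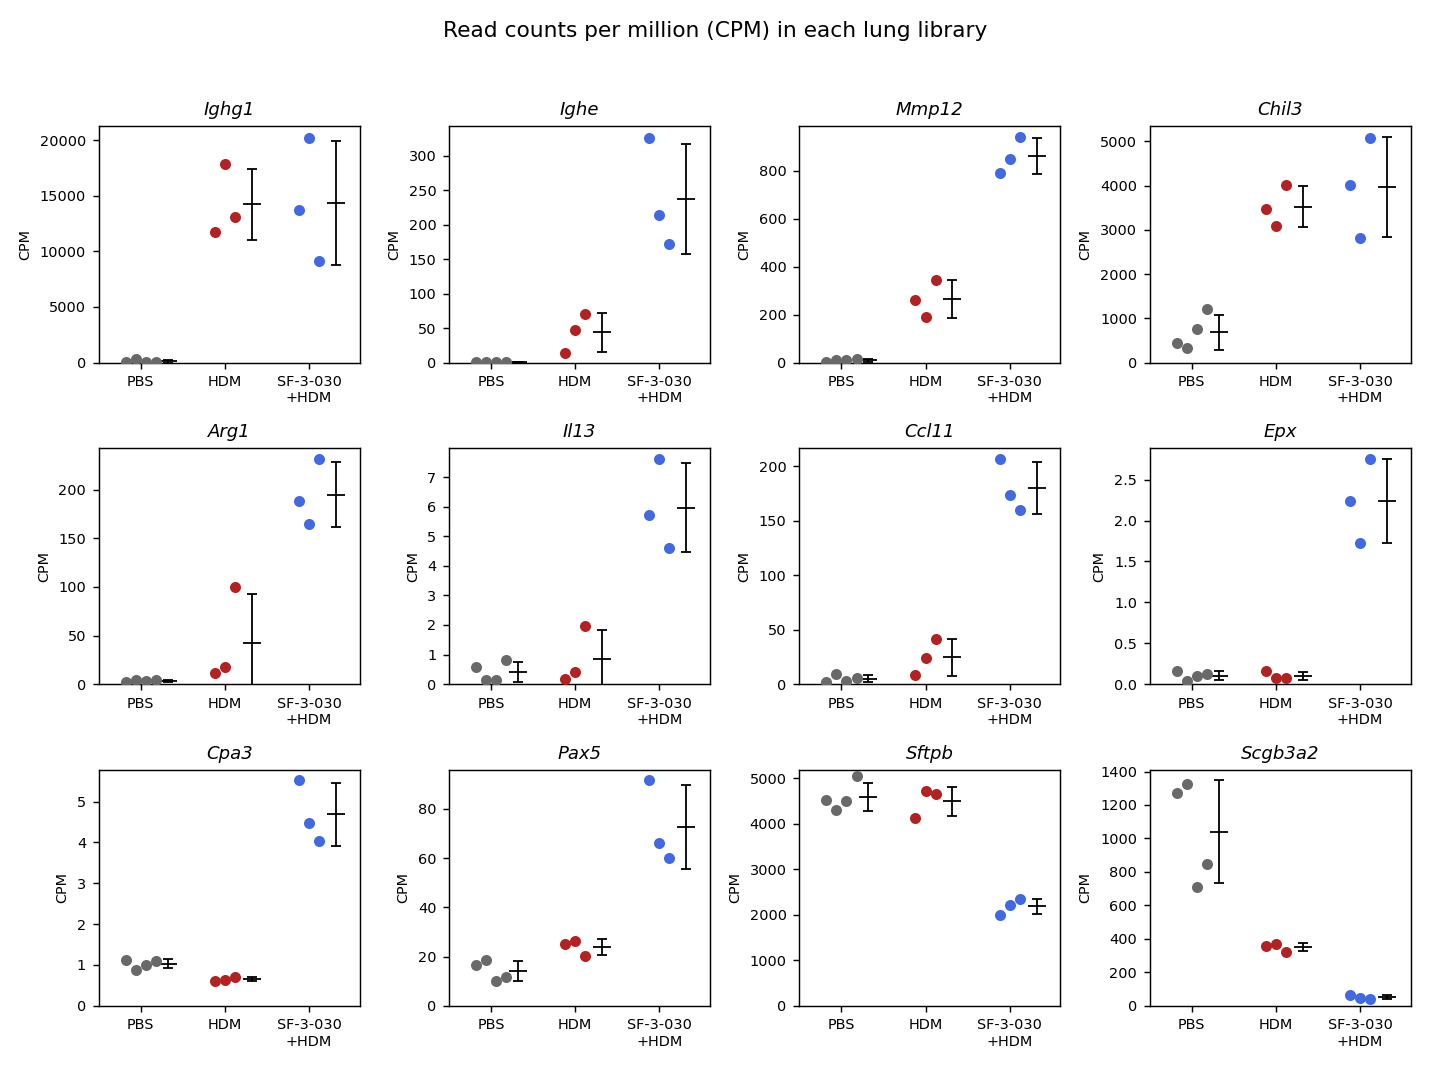
CPM of 12 genes in each library, on linear axes that start at 0; points are libraries (n = 4 for PBS and n = 3 for the other groups), and the line and bar are the mean ± SD, with bars that would reach below 0 ended at the axis. Ighg1 averages 108 CPM in PBS and 14200 CPM in HDM, and Scgb3a2 averages 1040, 349 and 51.4 CPM in PBS, HDM and SF-3-030+HDM.

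Whether genes changed by allergen moved back under SF-3-030 was read from the overlap of the first and second comparisons, which share the HDM libraries. Of the 685 genes changed in HDM against PBS, 54 moved back and 99 moved further in the same direction. Genes independent between the comparisons would give 36.8 higher then lower (50 seen) and 20.9 higher in both (79 seen). In 20 simulations of unchanged groups sharing the HDM libraries 0 moved back, a count that decides nothing, since neither simulated comparison had calls. Part of the 54 may come from the shared libraries or the strain type. Across genes, the fold changes had a covariance of 0.312 (-0.249 simulated) and a Pearson correlation of 0.23 (-0.54 simulated). Among the 54 were 28 immunoglobulin variable segments and 24 protein-coding genes such as Cxcr3, a T cell chemokine receptor whose rise with HDM lost its call without HDM replicate 2 (edgeR adjusted p = 0.0571). The 4 that moved from lower to higher, chosen after their values were seen, were Wnt2, Iyd, Fgf18 and Bdkrb2. Bdkrb2 lost its HDM call without HDM replicate 2 (0.0592), and the other 3 lost their SF-3-030 calls without HDM replicates 1 or 3 or any SF-3-030+HDM replicate (0.0543 to 0.111), Iyd also without PBS replicate 4 or HDM replicate 2. Fgf18 lost its HDM call as well, without PBS replicates 2, 3 or 4, HDM replicates 1 or 3 or SF-3-030+HDM replicate 2 (0.052 to 0.113). The count of 54 became 82 without PBS replicate 1, 34 without PBS replicate 4, 20 without HDM replicate 2, and 21, 22 and 31 without SF-3-030+HDM replicates 1 to 3. The median shift of the HDM-changed genes toward PBS, as a share of the HDM change, averaged -0.171, where a negative share lies beyond HDM, away from PBS. It was read in HDM replicates 1 to 3 in turn (-0.362, -0.0847 and -0.067; SD 0.165), each with genes chosen in the other pair, so the choices overlap. The mean ran from -0.217 to -0.0844 without single PBS or SF-3-030+HDM libraries.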

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

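The tests of strain, of treatment alone, of male animals, of mixed male RNA, of library depth, of shared HDM libraries and of Y-linked reads in SF-3-030+HDM against HDM were chosen only after the result was seen.

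Of 149 gene levels checked in PBS, the only group with more than 3 libraries, 16 had 1 library far from the other 3 (gap over range above Dixon's 95% critical value), where chance gives about 1 in 20, or 7.4. In PBS replicate 2 the immediate early genes Fos (299 CPM, others 21 to 55.5) and Egr1 (401, others 14.8 to 62.5) and the ERK phosphatase gene Dusp6 (114, others 66.1 to 71.4) were high. So were Ighg1 (274, others 41.1 to 70.4), Slamf7 (11.2, others 6.18 to 6.38) and Cyp1a1, a dioxin-responsive oxidase (262, others 15.4 to 22.4). Low there were Acoxl (67.8, others 104 to 104), Spp1 (63.8, others 93.6 to 96) and Ear1 (7.55, others 22.6 to 23), which makes 9 of the 16 in that library. PBS replicate 1 was high in Retnlg (44.3, others 18.3 to 21.5), Irf7 (33.1, others 17.1 to 19.4), Foxj1 (241, others 139 to 156) and Pcna (79.7, others 62.7 to 64.5). It was low in Col12a1 (27.8, others 44 to 44.6) and Aplnr (47.9, others 58.2 to 60.2). PBS replicate 4 was high in the clock gene Arntl (18.2, others 10.3 to 11.4).

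The 3 SF-3-030+HDM libraries stand apart from the other 7 in genes that are on in one set and off in the other: 7 genes pass 10 CPM on one side and stay under 1 CPM on the other, and the highest of the other splits into 3 and 7 libraries gives 2. All 5 genes of a panel known to differ between BALB/c and C57BL/6 mice (H2-Ea-ps, Gbp2b, Ifi202b, Tpsab1 and Apobec3) parted the libraries without overlap, in the direction that makes SF-3-030+HDM the BALB/c type. The first 4 were picked from their values, which leaves 1, Apobec3, too few to decide. A strain difference between these libraries and the other 7, all labelled BALB/c, stays open and may account for part of the genes called. The treatment alone cannot be told apart from it, because every library with the compound is in that set: 0 libraries without SF-3-030 have H2-Ea-ps above 10 CPM. Changes given in the report for SF-3-030 thus hold for the treatment, the strain type and anything else that goes with these 3 libraries together.

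Y-linked genes were read in 3 libraries labelled female, PBS replicate 2 and HDM replicates 2 and 3. Male RNA mixed into libraries of female animals is argued against, since the highest Xist level in the 3 is 4.63% of the lowest in the other 7. Male animals in these 3 libraries stay open, and may be the source, with Xist at no more than 2.71 CPM. Since 2 of 3 HDM libraries and 1 of 4 PBS libraries are of this kind, the uneven share could have made the HDM calls, but with a covariate for it the median change of the 685 called genes was 0.944 of that without (1.41 against 1.5, median SE 0.27 against 0.26). All 685 kept their sign and 392 their call, with a further term to estimate from the same 10 libraries. In SF-3-030+HDM against HDM, where 0 of 3 stand against 2 of 3, the median change of the 2491 called genes was 1.04 of that without (2.58 against 2.48, median SE 0.53 against 0.45). All 2491 kept their sign and 828 their call, with that wider SE. Both ratios are over genes called without the covariate. Such genes vary little within groups, so a ratio near 1 was likely beforehand and does not settle the part of the uneven share.

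Reads on genes silent in lung differ between libraries by up to 29.3-fold. Depth is argued against, since HDM replicate 2 and SF-3-030+HDM replicate 3, with nearly equal totals, differ 7.17-fold. Genomic DNA in the libraries stays open and may be the source: in HDM replicate 3, which has Y-linked reads, the X to autosome ratio of such reads was 0.524 (95% interval 0.473 to 0.573) of that in PBS replicates 1 and 4, as 1 X chromosome in place of a pair would give. For genes called lower in SF-3-030+HDM against HDM that average under 1 CPM, fewer such reads may be the cause, with olfactory and vomeronasal receptor genes at a fitted median of -5.89 (-3.43 with zeros at 3 counts over the group). For the 337 lower genes that average 10 CPM or more it is argued against, since background could reach as much as 50% of the fall in 0% of them. Those from 1 to 10 CPM were not tested.

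Other splits of the same libraries were fitted. For HDM against PBS, 3 of 35 splits gave as many calls as the real 685, so chance is not excluded for this count. The highest, 2695 calls, set HDM replicate 3 with PBS replicates 1 and 4 against the rest, the 3 libraries with the most background, which points to a structure of the samples; with background as a covariate HDM against PBS gave 819 higher and 152 lower. For SF-3-030+HDM against PBS, 1 of 35 splits, the real one, reached 7842, and the highest other gave 3856. Chance is argued against at a share under 0.05, though it is not excluded by so few splits. That split also follows strain type, so the count does not tell what made the calls. For SF-3-030+HDM against HDM, 10 splits are too few for a share under 0.05; the real split gave 2491, and the highest other 0. The same holds for genes moved back, at 54 for the real split (1 of 10) and 0 for the highest other. The HDM libraries shared by both comparisons stay open as a source of part of the 54, and so does the strain type of the SF-3-030+HDM libraries. Genes moved back in fits without 1 HDM library (55, 20 and 45 genes) kept 0.57, 1.33 and 0.715 of their change in the library left out (mean 0.872, SD 0.403), and 54, 20 and 44 of them lay on the same side there, but the spread between the 3 is too wide for the bound set.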

How the results depend on the processing

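The covariates for Y-linked expression and background, and the fits without the 3 libraries of either kind, were chosen after the data were seen; the rest were set earlier. Leaving out the Y-linked libraries leaves 1 HDM library, which is assumed to vary like the other groups. Values at a pseudocount and quantile scaling did not apply to counts and were not run. Why a count moved was not tested unless said.

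For HDM against PBS, 608 genes were higher and 77 lower. With DESeq2 these became 1057 and 359, with the replicate block 239 and 10, at a threshold of 0.01, which admits fewer genes, 248 and 15, with the Y-linked covariate 380 and 44, without the Y-linked libraries 241 and 9, and without the high-background libraries 208 and 35. The lower count also moved to 128 with upper-quartile scaling, 131 at 1 CPM in 3 libraries, 19 with only the 2 groups compared, and 152 with the background covariate. Leaving out 1 library gave 276 to 723 higher and 27 to 190 lower.

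For SF-3-030+HDM against HDM, 901 genes were higher and 1590 lower. With DESeq2 these became 1541 and 4201, with the replicate block 390 and 406, at a threshold of 0.01 298 and 297, with the Y-linked covariate 450 and 450, and without the Y-linked libraries 265 and 278. The higher count moved to 561 with upper-quartile scaling. The lower count moved to 535 with limma-voom, 2627 without a filter, 1023 at 1 CPM in 3 libraries, and 726 with the background covariate. Leaving out 1 library gave 323 to 1458 higher and 301 to 2263 lower.

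For SF-3-030+HDM against PBS, 3101 genes were higher and 4741 lower. The replicate block gave 1503 and 1129, a threshold of 0.01 1562 and 1310, and the background covariate 1729 and 1864. The lower count moved to 7674 with DESeq2, 2018 with limma-voom, 2806 at 1 CPM in 3 libraries, 2962 with only the 2 groups compared, and 2636 without the high-background libraries. Leaving out 1 library gave 1880 to 3121 higher and 2013 to 5234 lower. Higher genes made up 88.8%, 36.2% and 39.5% of calls in the 3 comparisons with edgeR, 74.6%, 26.8% and 31.8% with DESeq2, 60.3% and 59.1% in the latter 2 with limma-voom, and 27% in the last with upper-quartile scaling. DESeq2 gave no adjusted p for 23901, 15072 and 13304 of 45582 genes, which were counted as not called.

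The 54 genes moved back became 120 with DESeq2, 98 without a filter, 26 with the replicate block, 14 at a threshold of 0.01, 25 with the Y-linked covariate, 27 without the Y-linked libraries, and 20 to 82 leaving out 1 library. The shift share of -0.171 kept its sign in every alternative. It was -0.12 for genes chosen at a threshold of 0.01 and -0.0964 with means in place of medians.

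The 23 lists called in HDM against PBS became 4 with an estimated correlation and 11 in the directional fry test, and 21 to 25 leaving out 1 library. The 14 called in SF-3-030+HDM against HDM became 1, 7 and, in the mixed fry test, 26, and 13 to 17 leaving out 1 library. Reversed calls were the AP-1 list in HDM against PBS without PBS replicate 2 (0.0288, of a range of 0.00749 to 0.737 over single libraries left out), and in SF-3-030+HDM against HDM the plasma cell list (0.00899) and the NRF2 list (0.0373) with the Y-linked covariate and the AP-1 list (0.018) with the background covariate; none of these was called in the 10-library fit.

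Of 146 named or called list genes in HDM against PBS, 3353 combinations of gene and alternative gave 2664 with the call unchanged, 652 lost and 37 gained. For 148 genes in SF-3-030+HDM against HDM, 3392 combinations gave 2537 unchanged, 830 lost and 25 gained, and for 25 in SF-3-030+HDM against PBS, 574 gave 552, 17 and 5. No gene reversed. At this depth and spread the test recovered 12% or fewer of simulated changes of log2 size 1, so smaller changes are mostly not detectable here.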

Other observations

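The covariates and left-out sets of libraries named here were chosen only after the result was seen.

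Lists not yet described in HDM against PBS concern muscle, fat, blood, clock and stress genes. Clock genes were called higher as a list (camera adjusted p = 0.0298; adjusted p = 0.545 with an estimated correlation), but not without PBS replicates 1 (0.211) or 4 (0.0849) or HDM replicate 1 (0.359), with the replicate block (0.133) or at 1 CPM in 3 libraries (0.0503). The repressor genes Bhlhe41 (1.33 ± 0.22, edgeR adjusted p = 0.00813; 0.0522 without HDM replicate 2) and Bhlhe40 (0.95, adjusted p = 0.0491) rose and Arntl, which encodes the clock activator BMAL1, fell (-1.31 ± 0.23, adjusted p = 0.0114; 0.0728 without HDM replicate 2), of 18, with 5 higher and 3 lower adjusted over the list alone. Bhlhe40 lost its call without PBS replicates 3 or 4 or any HDM or SF-3-030+HDM replicate (0.0697 to 0.178). Skeletal muscle genes were called lower as a list (camera adjusted p = 0.00228; adjusted p = 0.269 with an estimated correlation; 0.0848 without HDM replicate 1). Of 13, Ckm, muscle creatine kinase, fell (-1.18, adjusted p = 0.0421) and Pvalb, parvalbumin, rose (2.74 ± 0.46, adjusted p = 0.00855), with 4 lower and 1 higher adjusted over the list alone. Ckm lost its call without any PBS replicate, HDM replicates 1 or 2 or SF-3-030+HDM replicate 3 (0.0526 to 0.16). The adipose list was lower (camera adjusted p = 0.00673; adjusted p = 0.532 with an estimated correlation), but not without PBS replicate 3 (0.0797), HDM replicate 3 (0.178) or the Y-linked libraries (0.521), nor with the Y-linked covariate (0.145). The erythroid list was lower (camera adjusted p = 0.0184; adjusted p = 0.576 with an estimated correlation), but not without PBS replicates 1 (0.237) or 2 (0.197) or HDM replicate 1 (0.33), nor at 1 CPM in 3 libraries (0.0502). In edgeR none of 13 adipose or 9 erythroid genes passed, with 1 higher and 1 lower adjusted over the adipose list alone, 3 and 1 at an unadjusted p under 0.05, 2 and 0 in DESeq2 and 0 in limma-voom.

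Further lists of that comparison were not called: smooth muscle (camera adjusted p = 0.619), alveolar type 2 (0.662), NRF2 target (0.158), thymocyte (0.766; median -0.20 and mean -0.10, while the test pointed up), squamous epithelium and cartilage (0.566) and neural genes (0.356). NRF2 target genes were called lower without PBS replicate 1 (0.02) or HDM replicate 2 (0.0154), with the Y-linked covariate (1.56e-05) and with the replicate block (0.0427). None of the 19 smooth muscle, 19 alveolar type 2, 22 NRF2 target, 8 thymocyte and 13 neural genes passed in edgeR or limma-voom. At an unadjusted p under 0.05 there were 0, 6, 5, 0 and 1 of these, DESeq2 called 0, 3, 2, 0 and 0, and adjusted over the list alone 1 alveolar type 2 gene was higher and 2 lower. The mixed fry test called the alveolar type 2 (0.0162) and squamous lists (0.000149). Of 13 squamous list genes, Krt5, a basal cell keratin, rose (2.40 ± 0.35, adjusted p = 0.00438), with 1 higher and 1 lower adjusted over the list alone. In SF-3-030+HDM against HDM, Krt5 (1.76 ± 0.36, adjusted p = 0.0137) and Trp63, its regulator (2.01 ± 0.54, adjusted p = 0.0413), rose, and the cartilage gene Col9a1, with no count in SF-3-030+HDM, was at least 11.1-fold lower, with 3 higher and 1 lower adjusted over the list alone, in a list that was not called (camera adjusted p = 0.131; 0.0382 without PBS replicate 1 and 0.000435 with background as a covariate). Krt5 lost that call without HDM replicate 2 (0.0536) or SF-3-030+HDM replicate 1 (0.0928), and Trp63 and Col9a1 without HDM replicates 2 or 3 or any SF-3-030+HDM replicate (0.065 to 0.12), Trp63 also without HDM replicate 1. Thymocyte genes Satb1 (1.28 ± 0.17, adjusted p = 0.00104) and Ccr9 (1.24, adjusted p = 0.0278; 0.0575 to 0.0965 without HDM or SF-3-030+HDM replicates 1 or 2) rose of 8, the same 2 adjusted over the list alone (list camera adjusted p = 0.235; median 0.02, mean -0.18, test up).

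Remaining lists of SF-3-030+HDM against HDM, with camera adjusted p, were T cell (0.27; called higher with the Y-linked covariate at 0.000725 and without the Y-linked libraries at 0.0105; 0.0288 without HDM replicate 2; no gene of 24 called by edgeR or limma-voom, 2 at an unadjusted p under 0.05 and 1 by DESeq2), monocyte (0.397; 0.038 without SF-3-030+HDM replicate 3 and just under 0.05 with background as a covariate), interferon-stimulated (0.55), extracellular matrix (0.0822; called higher without HDM replicate 3 at 0.00266 and without SF-3-030+HDM replicates 1 or 2 at 0.0048 and 0.0251, with the Y-linked covariate at 0.00514, without the Y-linked libraries at 0.00382 and with the replicate block at 0.0283), smooth muscle (0.29; 0.000496 without HDM replicate 3 and 0.00111 without the Y-linked libraries) and ciliated genes (0.273; called lower without HDM replicate 3 at 0.0219 or SF-3-030+HDM replicate 1 at 0.00745, with background as a covariate at 0.036 and at 1 CPM in 3 libraries at 0.0481). Others were endothelial (0.131; 0.0388 without SF-3-030+HDM replicate 1), NRF2 target (0.937; median 0.11, mean -0.05, test down; higher with the Y-linked covariate at 0.0373 and lower with the background covariate at 0.0115), clock (0.941; 0.0449 with background as a covariate), skeletal muscle (0.152), neural (0.935) and erythroid genes, which were called lower (0.0253; adjusted p = 0.585 with an estimated correlation; 0.185 without HDM replicate 2, 0.0727 without SF-3-030+HDM replicate 2, 0.52 with the Y-linked covariate, 0.187 with the background covariate and 0.894 without the Y-linked libraries). In the matrix list 5 genes rose and 3 fell of 36, with 6 and 4 adjusted over the list alone, led by the urokinase gene Plau (1.14 ± 0.17, adjusted p = 0.0025) and the osteopontin gene Spp1 (1.11 ± 0.20, adjusted p = 0.00705), which kept their calls without each single library; Mmp12, Mmp13 and Adam8 rose too. The elastin gene Eln (-1.60 ± 0.31, adjusted p = 0.0113; 0.065 to 0.0672 without SF-3-030+HDM replicates 1 or 2) fell, as did Mmp3 and Col12a1, which were chosen after their values were seen. Mmp12, Mmp13, Mmp3, Adam8 and Col12a1 lost their calls without HDM replicates 1 or 2 or any SF-3-030+HDM replicate (0.0542 to 0.154), and the first 3 also without HDM replicate 3.

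The mixed fry test called the monocyte (0.0035), interferon-stimulated (0.0418), matrix (4.92e-06), NRF2 target (0.00257), clock (0.0136), thymocyte (3e-06), skeletal muscle (0.00017), squamous (3.3e-05) and neural lists (1.99e-07). In the other lists of that comparison few genes passed. Siglech, a plasmacytoid dendritic cell lectin (1.53 ± 0.37, adjusted p = 0.0304), rose and Flt3 (-1.06 ± 0.25, adjusted p = 0.0294) fell of 24 monocyte list genes, also adjusted over the list alone. Mx2, an antiviral GTPase (1.11 ± 0.28, adjusted p = 0.0353), rose of 27 interferon-stimulated genes and Foxj1, the ciliogenesis factor (-0.74 ± 0.20, adjusted p = 0.0417), fell of 22 ciliated genes, neither adjusted over the list alone. The apelin receptor gene Aplnr (0.89 ± 0.22, adjusted p = 0.0323) rose of 20 endothelial genes, the NRF2 targets Osgin1 (adjusted p = 0.00623) and Gstm3 (-1.41 ± 0.39, adjusted p = 0.0447) fell of 22, and Nr1d1, a clock repressor (-1.06 ± 0.23, adjusted p = 0.0178), fell of 18. Adjusted over the list alone, 1 endothelial gene was higher, 2 NRF2 targets were higher and 3 lower, and 1 clock gene was lower. Of 13 skeletal muscle genes the myosin genes Myh1 (-3.87 ± 0.80, adjusted p = 0.0157) and Myh2, with 1 count in SF-3-030+HDM (ratio 48.5, counting interval 8.7 to 1910), and Ckm (-1.35 ± 0.29, adjusted p = 0.0179) fell, and 4 did adjusted over the list alone. The adhesion gene Ncam1 fell of 13 neural genes (-1.75 ± 0.32, adjusted p = 0.00712), also adjusted over the list alone, and kept its call without each single library. Osgin1 lost its call without SF-3-030+HDM replicate 2 (0.0597), Myh1 without replicates 1 (0.0786) or 2 (0.0807) of that group, Myh2 without HDM replicate 2 or SF-3-030+HDM replicates 2 or 3 (0.0554 to 0.0844), and Ckm without replicates 2 or 3 of either group (0.0606 to 0.068). The others lost theirs without HDM replicate 2 or any SF-3-030+HDM replicate (0.0502 to 0.158), Siglech, Mx2 and Flt3 also without HDM replicate 1, all but Flt3 and Nr1d1 without HDM replicate 3, and Foxj1 and Gstm3 without PBS replicate 4.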
